A study of Mus musculus with 8 samples.

How the data were processed

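PolyA-selected RNA was sequenced in 8 libraries from 2 stable mouse B cell lines, a control line and a line named for the microRNA miR-148a, each unstimulated or treated with anti-IgM at 2 ug/ml over 14 h. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a directional kit. The authors deposited 1 table of estimated counts per gene symbol, which are expected counts that need not be whole and are not normalised. Per the submitters' processing notes, CASAVA 1.8, cutadapt, TopHat2 2.0.13, Bowtie2, Partek 6.15.0730 and edgeR were used, with the builds mm10 and GRCm38. The notes give no role or order for these names, and the annotation behind the symbols and the strand setting of the counting are not given in the sources used here. Whether reads from overlapping, antisense or near-identical genes were told apart is therefore not known.

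Groups were taken from the sample labels, 4 groups of 2 libraries. The replicate number follows the run prefix in the labels, 137 for replicate 1 and 143 for replicate 2, so each run holds 1 library of every group. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than sampling noise in each group, with a mean chi-square per gene of 9.81 to 14.0 on 1 degree of freedom. Same-numbered libraries deviated together from their group means in all 6 pairs of groups (Pearson's r across genes 0.495 to 0.569, genes not being independent replicates), and the second principal component separated the runs. The numbers therefore pair the libraries by run. The planned test has no block, and values with the replicate number as a block are given beside reported results where they change a call or move a count by more than 1.5 times.

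The table had 24081 rows. Names turned into calendar dates stood in 27 rows, 0.213% to 0.235% of each library's counts, and these rows were left out because they name no gene. Between 9.11% and 12.4% of the values of a library were not whole, and estimated counts were rounded to whole numbers before the test. Totals ran from 5810227 to 18660373 counts per library, a ratio of 3.21, and 3 counts corresponded to 0.166 to 0.502 CPM (counts scaled to the library total and the TMM factor). Such floors cover counting error only. No column of another sample was present.

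Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15. The test was edgeR's quasi-likelihood F test on the counts of all 8 libraries with 4 group means (filterByExpr by group, TMM factors), with Benjamini-Hochberg adjustment over the 11291 genes that passed the filter and a threshold of 0.05. The 4 residual degrees of freedom are shared by all groups. The biological coefficient of variation was 11.1%, and 5.98% with the block, which left 3 degrees of freedom. The 5 contrasts were anti-IgM against unstimulated in each line, the miR-148a line against the control line in each condition, and the interaction. Gene values written with ± are log2 fold changes unless CPM is named. Errors written after ± are standard errors of a log2 fold change, or SD of CPM over n = 2 libraries where so named. CPM values are normalised with TMM factors. Run values are differences of log2 CPM between the libraries of 1 run, without a test.

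A set of 24 gene lists was fixed before the data were examined, as were the contrasts, the tests, the other settings to be tried and the rule for named genes. The lists held a study list of 3 genes the study's authors are known to have followed, with Gadd45a and Bcl2l11 among them, microRNA targets from the literature, B cell receptor activation genes, pro-apoptotic BCL2 family members, anti-apoptotic genes, mitosis, DNA replication, growth arrest, p53 targets, FOXO targets, ribosome biogenesis, glycolysis, cholesterol synthesis, the unfolded protein and integrated stress response, interferon-stimulated genes, B lineage genes, plasma cell genes, NF-kB genes, MHC class II genes, heat shock genes, and markers of T cells, of monocytes and macrophages, of fibroblasts and of erythroid cells. The fibroblast and erythroid lists had 1 measured member each and were not tested as sets. Lists were tested with camera in limma (inter-gene correlation preset at 0.01, adjusted over the lists of a contrast), and again with an estimated correlation and with fry.

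Named genes were, per contrast, the 10 with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean log2 CPM of at least 1 and the same sign in both runs (5 and 5 for the interaction), without unnamed predicted genes. Added to these were the study list, Mir148a and up to 4 called members of each list with the largest absolute change, or up to 2 uncalled members with the highest expression. Some genes that this rule takes are not reported here, though they stay in the list tests and the counts of called genes, and 1 not called in the planned test is left out of the named-gene counts under other settings.

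Sites for the miR-148 seed (nucleotides 2 to 8) were searched in the longest annotated 3' UTR of GENCODE M21 on GRCm38. Of 24054 named rows, 22838 matched by symbol, 843 by an older symbol and 373 not at all, and 20045 had a 3' UTR. Genes with a 7mer-m8 or 8mer site were compared with the other tested genes by camera and by the difference of medians, and the seed word was ranked among words made of the same 7 bases, of which 603 occurred in at least 50 genes.

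The steps were tested on simulated counts with 200 changed genes, in a single draw per contrast. The simulated libraries had no run effect shared by same-numbered libraries. Far fewer genes changed in them than were called in either response of the deposited data. The shares below therefore describe the simulated setting only. For the control line's response, 31.3%, 73.1% and 77.3% of genes changed 1.5, 2 and 3 times were recovered among 11166 genes, and 3.20% of the calls were unchanged genes. For that of the miR-148a line they were 25.4%, 82.1% and 87.9% among 11155 genes, with 9.72% unchanged. For the line differences they were 29.9%, 79.1% and 89.4% among 11156 genes without stimulation, with 6.38% unchanged, and 23.9%, 55.2% and 80.3% among 11159 genes with anti-IgM, with 6.19% unchanged. For the interaction, 5.97%, 58.2% and 81.8% were recovered among 11160 genes, and 9.35% of the calls were unchanged genes. Alternatives were RLE size factors, DESeq2, limma-voom, no filter, a filter of at least 1 CPM in 4 libraries, the replicate block, only the libraries of the groups compared, a threshold of 0.01, and leaving out each library in turn. Libraries thinned to the smallest total, and both anti-IgM libraries of a replicate number left out together, were added after the data were seen. Fits with libraries left out had no block, so a group left with 1 library stood for 1 run only. The difference between the runs then entered its fold changes.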

Results

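Transcripts were measured in 2 stable lines derived from WEHI-231, a mouse immature B cell lymphoma line that stops growing and dies when its B cell receptor is crosslinked. A control line and a line named for miR-148a were each sampled unstimulated and after 14 h of anti-IgM, an antibody that crosslinks the receptor, with 2 libraries per group. Total counts of replicates 1 and 2 were 18660373 and 11391702 in the unstimulated and 5810227 and 11348764 in the anti-IgM control group. In the miR-148a line they were 13455855 and 13242205 unstimulated and 5977803 and 10524385 with anti-IgM. The first principal component (49.4% of the variance) separated anti-IgM from unstimulated libraries, the second (21.1%) the 2 sequencing runs, and the third (14.4%) the lines. On the first component, replicate 2 of the anti-IgM miR-148a group lay at 39.9 and replicate 1 at 29.4.

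The label of the miR-148a line could not be checked on the microRNA itself, because polyA-selected libraries do not measure a mature microRNA. The Mir148a row held 1 count in replicate 1 of the unstimulated miR-148a group and 0 in the other 7 libraries, where 0 counts allow up to 0.502 CPM in the smallest of them. No difference was detectable at this depth.

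Bcl2l11 and Gadd45a belong to the study list, the genes that the study's authors are known to have followed as targets of miR-148a. Bcl2l11 encodes Bim, a pro-apoptotic BCL2 protein, and lies on chromosome 2 from 128126038 to 128162547 in GRCm38. Gadd45a lies on chromosome 6 from 67035096 to 67037457. Their longest 3' UTRs hold 3 and 1 miR-148 seed sites of 7mer-m8 or 8mer type, 1 of them an 8mer in each gene. In the control line Bcl2l11 rose with anti-IgM from 45.0 ± 0.147 to 128 ± 19.1 CPM (SD, n = 2), a log2 fold change of 1.52 ± 0.16 (adjusted p = 0.00117). In the miR-148a line it went from 42.4 ± 3.38 to 62.9 ± 14.3 CPM (SD, n = 2), a log2 fold change of 0.58 ± 0.17 (adjusted p = 0.0284). With anti-IgM, Bcl2l11 was lower in the miR-148a line by a log2 fold change of -1.02 ± 0.16 (adjusted p = 0.0207), and without stimulation the difference was -0.09 ± 0.16 (adjusted p = 0.920). The interaction for Bcl2l11 was -0.94 ± 0.23 on the log2 scale. It did not pass (adjusted p = 0.9996, or 0.0605 with the replicate block). The anti-IgM line difference of Bcl2l11 lost its call without replicate 1 (-1.16, adjusted p = 0.0546) or replicate 2 (-0.86, adjusted p = 0.146) of the anti-IgM control group. It lost the call too without replicate 2 of the anti-IgM miR-148a group (-1.29, adjusted p = 0.0529) and when fitted to the 4 anti-IgM libraries alone (-1.01, adjusted p = 0.0792). Its rise in the miR-148a line lost its call without replicate 1 (0.66, adjusted p = 0.0820) or replicate 2 (0.50, adjusted p = 0.145) of the unstimulated group and without replicate 2 of the anti-IgM group (0.31, adjusted p = 0.237).

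Gadd45a, a growth arrest and DNA damage gene, was at most 1.84 CPM in any library and passed no test, with log2 fold changes of 0.57 ± 0.60 and -0.60 ± 0.59 for the responses and 0.85 ± 0.55 and -0.31 ± 0.64 for the line differences. The study list as a whole was lower in the miR-148a line with anti-IgM (camera adjusted p = 0.00108, adjusted p = 0.475 with an estimated correlation), and Bcl2l11 fell there over all genes. The authors are known to have followed these genes in such cells, so the list is not independent evidence of its direction.

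**Figure D1:**
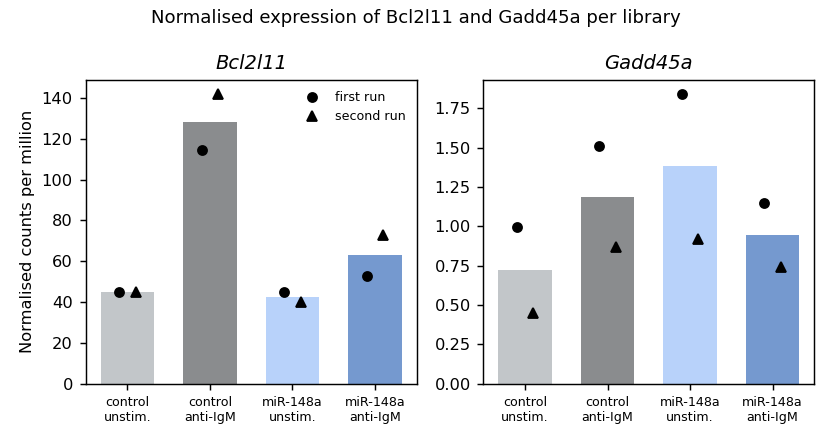
Normalised expression in CPM (y axis, linear from 0) of Bcl2l11 and Gadd45a in the 4 groups (x axis). Bars are means of 2 libraries, circles the first run and triangles the second, and Bcl2l11 with anti-IgM averages 128 in the control line and 62.9 in the miR-148a line.

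The first comparison asks how the control line responds to B cell receptor stimulation. Interferon-stimulated genes rose in 11 of 19 (camera adjusted p = 1.99e-11, adjusted p = 0.0343 with an estimated correlation). Gbp2, an interferon-induced GTPase, rose by a log2 fold change of 2.70 ± 0.21, Irf7, a transcription factor of the interferon response, by 2.67 ± 0.24, Oas2 by 2.59 ± 0.41 and Zbp1, a nucleic acid sensor, by 2.21 ± 0.23. Cholesterol synthesis genes fell in 14 of 20 (camera adjusted p = 8.71e-12, adjusted p = 0.274 with an estimated correlation). Msmo1 was at -1.15 ± 0.17, Idi1 at -1.01 ± 0.21, Mvd at -0.83 ± 0.11 and Fdps at -0.79 ± 0.11. The largest rises among named genes were Socs3, an inhibitor of cytokine signalling (4.06 ± 0.39), Csf1, a macrophage growth factor (3.66 ± 0.49), Tgm2 (3.20 ± 0.34), and S100a6 (3.18 ± 0.34). Epb4.1l1 (3.11 ± 0.37), Gadd45g (3.09 ± 0.39), Phactr1 (2.99 ± 0.33), Inadl (2.96 ± 0.37), Tgfb3 (2.95 ± 0.28) and Nol4l (2.93 ± 0.29) came next. The largest falls were Ncan (-2.86 ± 0.29), Cdh22 (-2.59 ± 0.22), Fam129c (-2.44 ± 0.18), Trpm5 (-2.38 ± 0.29), Glt25d1 (-2.29 ± 0.17), Hpn (-2.19 ± 0.39), the B lineage surface protein Ly6d (-2.14 ± 0.18), Ttn (-2.11 ± 0.61), Ip6k3 (-2.09 ± 0.29) and the kinase Bmx (-2.07 ± 0.37). These 20 genes had adjusted p values of at most 0.0440 (Ttn).

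Of 11291 genes tested, 1925 passed in the control line, 1084 higher and 841 lower with anti-IgM, and 3929 (1989 higher, 1940 lower) with the replicate block. More genes were lower than higher without a filter (972 higher, 1244 lower) and by DESeq2 (827 and 883). Each of the 1925 had the same sign in both runs. The count was 931 without replicate 1 and 540 without replicate 2 of the unstimulated control group, and 647 and 1207 without replicates 1 and 2 of the anti-IgM control group. Of 85 named genes called here, 37 lost their call without replicate 2 of the unstimulated control group, 33 and 24 without replicates 1 and 2 of the anti-IgM group, and 19 without replicate 1 of the unstimulated group. Without replicates 1 and 2 of the unstimulated miR-148a group 9 and 8 did, and without either anti-IgM miR-148a library 2.

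Of the interferon-stimulated genes none fell in the control line, and 13 rose when adjusted over the list alone. The list had a median log2 fold change of 1.05 (0.83 and 0.99 in the runs) and is the list of this comparison that also passed with an estimated correlation. It no longer passed when the estimated correlation and the block were combined (adjusted p = 0.141). Cholesterol synthesis genes had a median of -0.60 (-0.54 and -0.66), with 18 lower when adjusted over the list alone. Ribosome biogenesis genes fell in 18 of 25 (23 adjusted over the list alone), median -0.55 (-0.71 and -0.48; camera adjusted p = 2.80e-11, adjusted p = 0.282 with an estimated correlation). Among them were the nucleolar genes Gnl3 (-1.12 ± 0.20), Rrs1 (-1.06 ± 0.27) and Ddx21 (-0.82 ± 0.17) and the polyamine enzyme Odc1 (-0.81 ± 0.14). Unfolded protein and stress response genes fell in 15 of 20 (16 adjusted over the list alone), median -0.56 (-0.53 in each run; camera adjusted p = 1.48e-09, adjusted p = 0.282 with an estimated correlation). Chac1 was at -1.18 ± 0.32, Herpud1 at -1.11 ± 0.13, Sdf2l1 at -0.88 ± 0.18 and asparagine synthetase, Asns, at -0.80 ± 0.15.

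FOXO targets rose in 8 of 14 (10 adjusted over the list alone), median 0.84 (0.77 and 0.97; camera adjusted p = 1.56e-06, adjusted p = 0.274 with an estimated correlation). Bcl6 was at 2.22 ± 0.63, the PI3K inhibitor Pik3ip1 at 2.10 ± 0.30 and Sesn3 at 1.12 ± 0.12. Growth arrest genes rose in 7 of 14 (7 adjusted over the list alone), median 0.58 (0.51 and 0.72; camera adjusted p = 4.72e-05, adjusted p = 0.282 with an estimated correlation). They included the CDK inhibitors Cdkn2d (1.62 ± 0.17) and Cdkn1a (1.33 ± 0.27) and Ccng2 (0.78 ± 0.21). NF-kB genes fell in 11 of 19 and rose in 2 (11 and 3 adjusted over the list alone), median -0.43 (-0.56 and -0.33; camera adjusted p = 3.27e-05, adjusted p = 0.469 with an estimated correlation). The 4 that fell most include inhibitors of the pathway, Nfkbid (-1.69 ± 0.29), Tnfaip3 (-1.41 ± 0.17), Nfkbie (-1.18 ± 0.24) and Traf3 (-1.01 ± 0.13). Plasma cell genes fell in 4 of 9 (4, and 1 higher, adjusted over the list alone and with the block), median -0.38 (-0.28 and -0.46; camera adjusted p = 0.0234, adjusted p = 0.282 with an estimated correlation), with Irf4, a factor of plasma cell differentiation, at -1.40 ± 0.18, Creld2 at -0.51 ± 0.13, Mzb1 at -0.43 ± 0.10 and Xbp1 at -0.38 ± 0.11.

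Mitosis genes rose in 5 of 25 (5 adjusted over the list alone, 13 with the block), median 0.23 (0.29 and 0.13; camera adjusted p = 0.00690, adjusted p = 0.512 with an estimated correlation). Most changed were Nusap1 (0.64 ± 0.14), Ccnf, Cenpf and Aurka (0.47 each, SE 0.11, 0.10 and 0.13). Without replicate 1 of the anti-IgM control group the mitosis list no longer passed (adjusted p = 0.139). MHC class II genes rose in 2 of 11 (4 adjusted over the list alone, 5 with the block), Ciita, their transcriptional activator (1.35 ± 0.35), and H2-DMb2 (0.96 ± 0.28). The list median was 0.64 (0.31 and 0.88; camera adjusted p = 0.0260, adjusted p = 0.512 with an estimated correlation). The MHC class II list no longer passed without replicate 2 of the unstimulated (adjusted p = 0.142) or of the anti-IgM control group (adjusted p = 0.119). Pro-apoptotic BCL2 members did not pass as a list (camera adjusted p = 0.0927), although Bcl2l11, Bmf (1.499 ± 0.33) and Bak1 (0.63 ± 0.16) were among 4 of 9 that rose and Bid (-0.84 ± 0.11) fell.

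The other lists of this comparison did not pass camera. The p53 targets rose in 3 of 20 (5 adjusted over the list alone, 6 with the block and 1 lower). They include Trp53inp1 (1.73 ± 0.36) and Btg2 (0.73 ± 0.13). The list passed camera with the block (adjusted p = 0.121, and 0.0153 with the block), but not with the block and an estimated correlation (adjusted p = 0.395). The same held for the study list (adjusted p = 0.0621, then 0.0482 and 0.337), in which Bcl2l11 rose. B cell receptor activation genes went both ways, 6 up and 4 down of 23 (8 and 7 adjusted over the list alone, 9 and 8 with the block; adjusted p = 0.613), with Dusp4 (2.64 ± 0.53), Dusp6 (2.07 ± 0.57), Jun (1.84 ± 0.38) and Egr2 (1.59 ± 0.39) higher. The median (0.19) and mean (0.28) of this list were positive and its camera direction was down. Anti-apoptotic genes fell in 2 of 10, Birc3 (-0.82 ± 0.12) and Bcl2 (-0.68 ± 0.12), with a list adjusted p of 0.175. B lineage genes rose in 6 of 27 and fell in 1 (10 and 6 with the block; adjusted p = 0.300), led by Cd38 (1.51 ± 0.19) and Vpreb3 (1.47 ± 0.25), with a median of -0.07 and a mean of 0.16. Glycolysis (3 up, 1 down of 17; adjusted p = 0.376), literature targets (4 up of 18; adjusted p = 0.553), heat shock (1 up of 7; adjusted p = 0.606) and DNA replication genes (1 down of 30, Mcm2 at -0.34 ± 0.09; adjusted p = 0.613) did not pass. With the block 5 up and 2 down, 5 and 3, 1 and 2, and 2 and 4 of them were called. The DNA replication median (0.02) and mean (-0.02) differed in sign.

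Markers of other cell types were mostly at the floor. Lyz2, S100a8 and S100a9, abundant transcripts of macrophages and neutrophils, had 0 counts in all 8 libraries, and Csf1r reached at most 1.33 CPM before TMM scaling. Of 4 measured monocyte and macrophage markers, Itgam rose in both lines, by 3.50 ± 0.40 in the control line (adjusted p = 0.00163) and 4.17 ± 0.39 in the miR-148a line (adjusted p = 0.000406), to at most 9.14 CPM before TMM scaling. That list passed in the miR-148a line (median 0.88, run values 0.92 and 1.02, camera adjusted p = 0.0242, adjusted p = 0.271 with an estimated correlation; 1 of 4 rose, 2 adjusted over the list alone and 2 with the block) and not in the control line (median 0.52, adjusted p = 0.0927). Of 2 measured T cell markers, Lck, which B lymphoma lines can also express, rose by 0.53 ± 0.14 and 0.67 ± 0.14 in the lines, and the list did not pass (adjusted p = 0.184 and 0.309; both markers rose with the block in the control line). The fibroblast list had Vim alone, which rose by 1.04 ± 0.15 (adjusted p = 0.00369) and 1.38 ± 0.15 (adjusted p = 0.000688). The erythroid list had Alas2 alone, at 0.24 ± 0.75 and 0.51 ± 0.78, which did not pass.

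**Figure D2:**
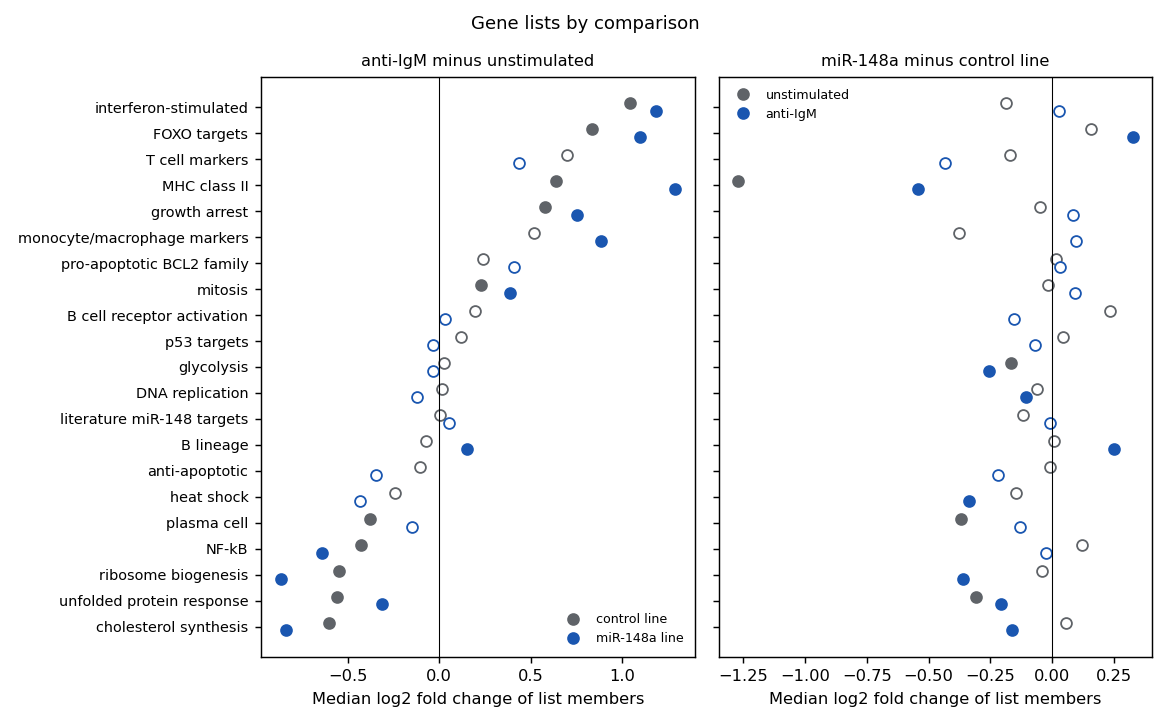
Median log2 fold change of the members of 21 gene lists (x axis) per list (y axis). The left panel shows anti-IgM minus unstimulated in the control (grey) and miR-148a line (blue), the right panel the miR-148a minus the control line without (grey) and with anti-IgM (blue), and filled circles passed camera with the preset correlation. MHC class II genes lie at -1.27 in the unstimulated line difference.

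The second comparison asks the same of the miR-148a line. Cholesterol synthesis genes fell in 19 of 20, with Idi1 at a log2 fold change of -1.39 ± 0.22, Msmo1 at -1.29 ± 0.17, Hmgcs1 at -1.13 ± 0.17 and Lss at -1.07 ± 0.12. Ribosome biogenesis genes fell in 24 of 25, with Gnl3 at -1.54 ± 0.20, Rrs1 at -1.48 ± 0.27, Srm at -1.25 ± 0.19 and Ddx21 at -1.22 ± 0.17. Each list had a camera adjusted p of 6.71e-15, and an adjusted p of 0.271 with an estimated correlation. Myc, a driver of ribosome biogenesis, fell by 2.08 on the log2 scale (SE 0.32, adjusted p = 0.00208). The largest rises were Slfn5 (3.56 ± 0.35), Tgm2 (3.43 ± 0.30), S100a6 (3.21 ± 0.34), Socs3 (3.19 ± 0.37), and Gadd45g (3.10 ± 0.39). They were followed by the metallothionein Mt2 (3.10 ± 0.30), Acsbg1 (3.09 ± 0.41), Gm2a (2.99 ± 0.31), Camkk1 (2.89 ± 0.18) and Sec14l4 (2.87 ± 0.35). The largest falls, besides Myc, were Cd83, a B cell activation marker (-4.06 ± 0.66), Ttn (-2.84 ± 0.59), Dclk1 (-2.74 ± 0.35), Hpn (-2.70 ± 0.39), Ncan (-2.40 ± 0.28), Pappa2 (-2.34 ± 0.62), Chac1 (-2.31 ± 0.36), Bmx (-2.18 ± 0.33) and the chemokine receptor Ackr3 (-2.12 ± 0.14). These 20 genes had adjusted p values of at most 0.022 (Pappa2).

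In the miR-148a line 3238 genes passed, 1659 higher and 1579 lower with anti-IgM, and 5205 (2569 higher, 2636 lower) with the replicate block. More genes were lower than higher also by DESeq2 (1315 higher, 1397 lower), without a filter (1636 and 1664) and without replicate 1 of the anti-IgM miR-148a group (1499 and 1656). The count was 1628 without replicate 2 of the anti-IgM miR-148a group, and 1481 and 2023 without replicates 1 and 2 of the unstimulated miR-148a group. Of 88 named genes called here, 16 lost their call without that anti-IgM library, and 14 and 9 without those unstimulated libraries. It was 4 without replicate 1 of the anti-IgM miR-148a group and 2 without any 1 library of the control line.

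Ribosome biogenesis genes had a median of -0.86 (-0.84 and -0.995 in the runs), and cholesterol synthesis genes of -0.84 (-0.70 and -0.92), with 25 and 19 lower when adjusted over the list alone. Interferon-stimulated genes rose in 13 of 19 and 1 fell (13 and 1 adjusted over the list alone), median 1.18 (1.097 and 1.09; camera adjusted p = 6.49e-09, adjusted p = 0.0707 with an estimated correlation). Oas2 was at 4.01 ± 0.47, Xaf1 at 3.80 ± 1.06, Zbp1 at 2.69 ± 0.23 and Gbp2 at 2.45 ± 0.19. FOXO targets rose in 10 of 14 (12 adjusted over the list alone), median 1.096 (1.02 and 1.01; camera adjusted p = 2.45e-07, adjusted p = 0.271 with an estimated correlation). Pik3ip1 was at 2.34 ± 0.28 and Klf2 at 1.23 ± 0.17. NF-kB genes fell in 13 of 19 and rose in 2 (13 and 3 adjusted over the list alone), median -0.64 (-0.68 and -0.69; camera adjusted p = 1.38e-05, adjusted p = 0.424 with an estimated correlation). Nfkbid (-1.94 ± 0.29), Tnfaip3 (-1.74 ± 0.18), Nfkbie (-1.73 ± 0.25) and Traf3 (-1.19 ± 0.13), all of them restraints on the pathway, led this list.

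Unfolded protein and stress response genes fell in 7 of 20 (8 adjusted over the list alone, 12 with the block), median -0.31 (-0.18 and -0.53; camera adjusted p = 2.67e-05, adjusted p = 0.424 with an estimated correlation). Asns was at -1.07 ± 0.15 and Atf4 at -1.02 ± 0.14. Growth arrest genes rose in 7 of 14 (8 adjusted over the list alone), median 0.76 (0.64 and 0.67; camera adjusted p = 3.88e-05, adjusted p = 0.271 with an estimated correlation). Cdkn2d was at 2.14 ± 0.18, Cdkn1a at 1.26 ± 0.27 and Ccng2 at 1.21 ± 0.21. Mitosis genes rose in 12 of 25 (14 adjusted over the list alone, 19 with the block), median 0.39 (0.48 and 0.29; camera adjusted p = 7.96e-05, adjusted p = 0.424 with an estimated correlation). Most changed were Nusap1 (0.77 ± 0.14), Ccnf (0.73 ± 0.11), Kif20a (0.65 ± 0.11) and Kif23 (0.63 ± 0.14). MHC class II genes rose in 8 of 11 (11 adjusted over the list alone), median 1.29 (0.80 and 1.58; camera adjusted p = 0.000143, adjusted p = 0.424 with an estimated correlation). Ciita was at 2.37 ± 0.39, H2-DMb1 at 1.93 ± 0.36, H2-Ob at 1.65 ± 0.54 and H2-DMa at 1.54 ± 0.24. B lineage genes rose in 11 of 27 and 1 fell (11 and 3 adjusted over the list alone, 11 and 6 with the block), median 0.15 (0.08 and 0.21; camera adjusted p = 0.00166, adjusted p = 0.424 with an estimated correlation). Vpreb3 was at 2.55 ± 0.26, Cd38 at 2.22 ± 0.20, Fcrla at 1.83 ± 0.20 and Fcgr2b at 1.61 ± 0.20. The 11 lists that passed in the miR-148a line also passed with any 1 library left out.

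The remaining lists did not pass in the miR-148a line. B cell receptor activation genes split into 5 up and 7 down of 23 (8 and 9 with the block; adjusted p = 0.109). Dusp4 was at 2.31 ± 0.63 and Irf4 at -1.87 ± 0.18, and the list had a median of 0.03 and a mean of -0.20. Anti-apoptotic genes fell in 4 of 10 and 1 rose (6 and 2 with the block; adjusted p = 0.165), with Bcl2a1b, whose reads can be shared with near-identical copies, at -0.84 ± 0.21, Birc3 at -0.73 ± 0.12, Bcl2 at -0.58 ± 0.13 and Mcl1 at 0.39 ± 0.13. Pro-apoptotic BCL2 members rose in 4 of 9 and 1 fell (adjusted p = 0.309). Bmf was at 1.89 ± 0.33, Bak1 at 0.93 ± 0.17 and Bid at -0.82 ± 0.11. Literature targets rose in 5 of 18 and 1 fell (6 and 2 with the block; adjusted p = 0.193). Cdc25b was at 2.00 ± 0.23 and Abca1 at 1.43 ± 0.21. Heat shock genes fell in 3 of 7 and 1 rose (5 fell with the block; adjusted p = 0.204), and plasma cell genes fell in 1 of 9 and 1 rose (4 fell with the block; adjusted p = 0.249). DNA replication (1 up, 1 down of 30, 2 and 7 with the block; adjusted p = 0.309), p53 targets (3 up, 1 down of 20, 8 and 1 with the block; adjusted p = 0.371), glycolysis (5 up, 5 down of 17; adjusted p = 0.844) and the study list (Bcl2l11 up; adjusted p = 0.964) also did not pass. Median and mean differed in sign for p53 targets (-0.03 and 0.16) and glycolysis (-0.03 and 0.05).

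The responses of the lines were then compared. Of the genes tested, 905 rose in both lines where independent lists would share 159, and 737 fell in both where independent lists would share 118, while none went opposite ways. With the replicate block 3288 genes were shared in direction. Across genes the log2 fold changes had r = 0.798, genes not being independent replicates. Among the 1642 shared genes, 71.5% had the larger absolute change in the miR-148a line, 60.4% in the first run and 74.8% in the second.

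The interaction tests whether a gene responded differently in the lines, and it called no gene by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 484 genes, fewer than that threshold alone would give on average, and 1315 with the replicate block. The planned fit left the run difference in its spread, with a biological coefficient of variation of 11.1% against 5.98% with the block. The lack of calls is therefore no evidence that the lines respond alike. limma-voom also called 0, and DESeq2 called 1, Tfrc, the transferrin receptor (log2 difference -0.87, adjusted p = 0.0408). With the replicate block 11 genes passed, 7 with a higher and 4 with a lower response in the miR-148a line. Higher were Klhl6 (0.89 ± 0.13), Cyth4 (0.79 ± 0.11), Lsp1 (0.74 ± 0.10), Ceacam1 (0.72 ± 0.12), Cnp (0.66 ± 0.11), Ckm (0.63 ± 0.11) and the predicted gene 1700088E04Rik, whose mean log2 CPM was -0.41. Lower were Pdgfb (-1.50 ± 0.25), Ccnb1ip1 (-0.92 ± 0.15), Tfrc (-0.89 ± 0.10, adjusted p = 0.00531) and Slc4a7 (-0.82 ± 0.13). These 11 genes were named after their values were seen.

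Lists whose interaction passed camera were led by ribosome biogenesis, lower in its response in the miR-148a line by a median of -0.32 (-0.07 and -0.52 in the runs; adjusted p = 3.18e-06), and B lineage genes, higher by 0.16 (0.25 and 0.15; adjusted p = 3.18e-06). MHC class II genes were higher in their response by 0.77 (0.45 and 0.43, adjusted p = 4.78e-05) and cholesterol synthesis lower by -0.33 (-0.27 and -0.34, adjusted p = 4.90e-05). The MHC class II list itself lay lower in the miR-148a line in both conditions, with medians of -1.27 unstimulated and -0.54 with anti-IgM. Also passing were mitosis, higher by 0.13 (0.18 and 0.09; adjusted p = 0.00150), B cell receptor activation, lower by -0.36 (-0.21 and -0.31; adjusted p = 0.00433), and FOXO targets, higher by 0.32 (0.21 and 0.33; adjusted p = 0.0386). The study list had a median of -0.94 (-1.11 and -0.79; adjusted p = 0.000564), without being independent evidence. None of the 8 passed with an estimated correlation (adjusted p = 0.396 to 0.479), and no member of any list was called by edgeR. Adjusted over the list alone Bcl2l11 of the study list passed, lower, and 0 members of the 7 other lists. The other 14 tested lists did not pass (adjusted p = 0.0700 to 0.869), and pro-apoptotic members differed in sign between median (0.02) and mean (-0.01). With the block, glycolysis (adjusted p = 0.0191) and heat shock (adjusted p = 0.00845) passed too, but not with the block and an estimated correlation (adjusted p = 0.543 each). Without replicate 2 of the anti-IgM miR-148a group, B cell receptor activation (adjusted p = 0.151), FOXO targets (0.412), ribosome biogenesis (0.0538), cholesterol (0.0744) and MHC class II (0.403) no longer passed. Without replicate 2 of the anti-IgM control group, B cell receptor activation and FOXO targets (0.289 each), mitosis (0.295) and ribosome biogenesis (0.0776) did not. FOXO targets were also lost without replicate 1 of the unstimulated control (0.507) or miR-148a group (0.124), B cell receptor activation without the latter library (0.139), and mitosis without replicate 1 of the anti-IgM miR-148a group (0.142).

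The third comparison asks how the unstimulated lines differ. In the miR-148a line the RNA-binding protein gene Celf2 was lower by a log2 fold change of -1.29 ± 0.12, Uhmk1 by -1.09 ± 0.15, Bcat1, an enzyme of branched-chain amino acid metabolism, by -1.09 ± 0.16, Arl6ip1 by -1.05 ± 0.11 and Bcap29 by -1.02 ± 0.10. The homeobox gene Cdx1 was higher by 2.10 ± 0.36, Jup, a junction protein, by 1.57 ± 0.20, the receptor Fzd6 by 1.44 ± 0.23, Igfn1 by 1.32 ± 0.18 and Camk2n1, an inhibitor of CaM kinase II, by 1.298 ± 0.15. Other named genes were Gkap1 (1.25 ± 0.15), Hspg2 (1.19 ± 0.15), Fgfr3 (1.11 ± 0.14), Jag2 (1.095 ± 0.18) and Fam83h (1.095 ± 0.15), and, lower, H2-Ea-ps (-2.33 ± 0.39), Ipcef1 (-1.80 ± 0.24), Myo1e (-1.04 ± 0.12), Chst11 (-0.98 ± 0.13) and Nxpe3 (-0.97 ± 0.15). H2-Ea-ps belongs to the MHC class II family, so its reads can be shared with other members. These 20 genes had adjusted p values from 0.0189 to 0.0499.

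Of 11291 genes, 55 passed between the unstimulated lines, 28 higher and 27 lower in the miR-148a line, and 823 (442 higher, 381 lower) with the replicate block. DESeq2 called 151, with 61 higher and 90 lower, and with RLE size factors 22 were higher and 29 lower. Without any 1 of the 4 unstimulated libraries, that is replicates 1 and 2 of the control and of the miR-148a group, 0 genes passed by edgeR, with 678 to 1006 genes at an unadjusted p under 0.05. All 21 named calls here were lost without each of them.

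Among the lists, MHC class II genes stood lowest, with a median of -1.27 in the unstimulated miR-148a line (-1.34 and -1.10 in the runs; camera adjusted p = 1.62e-14, adjusted p = 0.319 with an estimated correlation). None of its 11 members passed over all genes, and 8 did, all lower, when adjusted over the list alone and with the block. By fry the list did not pass (mixed test adjusted p = 0.0740, directional test adjusted p = 0.288). H2-Ab1 was at 17.9 ± 0.617 CPM in the control and 4.07 ± 0.769 CPM in the miR-148a group (SD, n = 2), Ciita at 34.0 ± 1.44 and 10.9 ± 4.69 CPM, and Cd74, the invariant chain, at 771 ± 159 and 483 ± 5.24 CPM. H2 genes resemble each other, so reads can be shared among them and their single values are uncertain. Unfolded protein and stress response genes had a median of -0.31 (-0.30 and -0.33; camera adjusted p = 8.39e-09, adjusted p = 0.664 with an estimated correlation), with 1 of 20 lower, the chaperone Calr (-0.67 ± 0.09; 10 lower adjusted over the list alone and with the block). Plasma cell genes had a median of -0.37 (-0.37 and -0.32; camera adjusted p = 0.000606, adjusted p = 0.319 with an estimated correlation), with 0 of 9 called (5 lower and 1 higher adjusted over the list alone, 4 and 1 with the block). Glycolysis had a median of -0.17 (-0.21 and -0.10; camera adjusted p = 0.0269, adjusted p = 0.664 with an estimated correlation), with 0 of 17 called (0 adjusted over the list alone, 4 lower with the block), and it did not pass without replicate 1 of the control (adjusted p = 0.413) or of the miR-148a group (0.0512).

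The other 18 tested lists did not pass between the unstimulated lines (adjusted p = 0.137 to 0.990), and none of their members was called over all genes. With the block, the members higher and lower were 6 and 4 of B lineage genes, 4 and 1 of B cell receptor activation, 2 and 5 of literature targets and 2 and 1 of interferon-stimulated genes. They were 1 and 1 for each of pro-apoptotic members, DNA replication and cholesterol. Higher alone were 3 p53 targets, 2 FOXO targets, 2 growth arrest genes and 1 NF-kB gene, and lower alone 2 mitosis genes and 1 each of heat shock genes, T cell markers and monocyte and macrophage markers. Adjusted over the list alone, 5 literature targets were lower and 1 higher of 18 (list adjusted p = 0.286). FOXO targets had a median of 0.16 (adjusted p = 0.137), B cell receptor activation 0.23 (0.229), NF-kB 0.12 (0.286), mitosis -0.02 (0.286), literature targets -0.12 (0.286) and DNA replication -0.06 (0.286). Monocyte and macrophage markers had a median of -0.38 (0.286), T cell markers -0.17 (0.303), cholesterol 0.05, anti-apoptotic genes -0.01 and heat shock -0.14 (0.324 each), p53 targets 0.04 (0.565), ribosome biogenesis -0.04 (0.647), growth arrest -0.05 (0.843) and pro-apoptotic members 0.02 (0.990). Signs of median, mean and test differed for B lineage genes (0.01, -0.02 and down, adjusted p = 0.836) and interferon-stimulated genes (-0.19, -0.10 and up, adjusted p = 0.919). The same held for pro-apoptotic members (0.02, 0.01 and down) and the study list (median -0.09, a positive mean and down, adjusted p = 0.728).

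**Figure D3:**
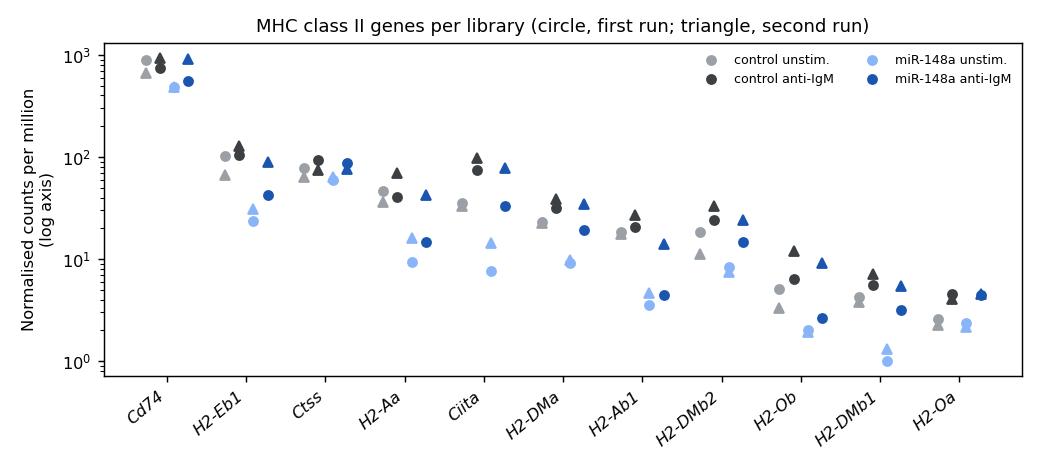
Normalised CPM (y axis, log scale) of 11 MHC class II genes (x axis) in each library, by group (colour) and run (shape). H2-Ab1 averages 17.9 in unstimulated control and 4.07 in unstimulated miR-148a libraries, and Ctss, a protease, 70.0 and 61.5.

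The fourth comparison asks how the lines differ under anti-IgM. The sphingosine receptor S1pr1 was higher in the miR-148a line by a log2 fold change of 1.51 ± 0.22 and the transcription factor Klf2 by 0.88 ± 0.17. Glycolytic Pfkp (-0.70 ± 0.14), Pkm (-0.52 ± 0.11) and Ldha (-0.49 ± 0.09) were lower, as were the chemokine Ccl22 (-1.47 ± 0.23), the adhesion molecule Alcam (-1.46 ± 0.27) and Tnfsf14 (-1.37 ± 0.21). The B lineage genes Spib (0.70 ± 0.09), Syk (0.54 ± 0.10) and Cd79a, a chain of the receptor complex (0.52 ± 0.10), were higher. Other named genes that were higher were Cdx1 (2.62 ± 0.42), Bai2 (2.50 ± 0.49), Igfn1 (1.86 ± 0.21), Camk2n1 (1.85 ± 0.16), Camsap3 (1.60 ± 0.33), Sec14l4 (1.53 ± 0.33) and Neurl1b (1.53 ± 0.28). Lower were Kcnk10 (-2.19 ± 0.40), Zfp365 (-1.88 ± 0.38), Tespa1 (-1.85 ± 0.28), Sh2d2a (-1.75 ± 0.30), Abra (-1.61 ± 0.34), Bcat1 (-1.47 ± 0.17) and Cacnb4 (-1.42 ± 0.27). Adjusted p values of these genes ran from 0.00942 (Camk2n1) to 0.0498 (Sec14l4).

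With anti-IgM 284 genes passed, 153 higher and 131 lower in the miR-148a line, and 1822 (892 higher, 930 lower) with the replicate block. The count was 24 (10 higher, 14 lower) without replicate 1 and 0 without replicate 2 of the anti-IgM control group (1439 at an unadjusted p under 0.05), and 3 without replicate 2 of the anti-IgM miR-148a group. It was 185 without replicate 1 or without replicate 2 of the unstimulated control group, and 114 and 116 without replicates 1 and 2 of the unstimulated miR-148a group. Of 34 named genes called here, 34 lost their call without replicate 2 of the anti-IgM control group, 32 without replicate 2 of the anti-IgM miR-148a group and 29 without replicate 1 of the anti-IgM control group. Without replicate 1 of the anti-IgM miR-148a group 15 did, without either unstimulated control library 12 and without either unstimulated miR-148a library 20. Fitted to the 4 anti-IgM libraries alone, 16 genes passed. Of the genes called in both line comparisons, 18 were higher and 21 lower in both, where independent lists would share 0.379 and 0.313, with 0 in opposite directions. With the block 469 were shared in direction.

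Ribosome biogenesis genes had a median of -0.36 with anti-IgM, carried by the second run (-0.02 and -0.68; camera adjusted p = 2.71e-05, adjusted p = 0.574 with an estimated correlation), with 0 of 25 called (5 lower adjusted over the list alone, 10 with the block). Glycolysis had a median of -0.25 (-0.33 and -0.17; camera adjusted p = 0.000283, adjusted p = 0.499 with an estimated correlation), with 3 of 17 lower (8 adjusted over the list alone, 9 with the block). B lineage genes had a median of 0.25 (0.21 and 0.31; camera adjusted p = 0.000402, adjusted p = 0.574 with an estimated correlation), with 3 of 27 higher (5, and 1 lower, adjusted over the list alone; 11 and 1 with the block). FOXO targets had a median of 0.33 (0.19 and 0.49; camera adjusted p = 0.000402, adjusted p = 0.574 with an estimated correlation), with 3 of 14 higher (4 adjusted over the list alone, 6 with the block). Unfolded protein and stress response genes had a median of -0.21 (-0.06 and -0.41; camera adjusted p = 0.000553, adjusted p = 0.574 with an estimated correlation), with 1 of 20 lower, Calr (-0.50 ± 0.09; 4 adjusted over the list alone, 6 with the block). MHC class II genes had a median of -0.54 (-0.79 and -0.38; camera adjusted p = 0.00416, adjusted p = 0.574 with an estimated correlation) with 0 of 11 called (0 adjusted over the list alone, 4 lower with the block).

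Heat shock (median -0.34; -0.21 and -0.48; camera adjusted p = 0.0163), cholesterol (-0.16; -0.01 and -0.24; 0.0184) and DNA replication genes (-0.11; -0.15 and -0.07; 0.0348) also passed with anti-IgM, and did not with an estimated correlation (adjusted p = 0.574, 0.574 and 0.499), with no member called. Adjusted over the list alone 1, 2 and 0 of their members were lower, and with the block 4, 5 and 5, with 1 DNA replication gene higher. Without replicate 1 of the anti-IgM control group these 3 lists no longer passed (adjusted p = 0.0626, 0.0634 and 0.122). Without replicate 2 of the anti-IgM miR-148a group heat shock (0.288), cholesterol (0.534), the unfolded protein and stress response (0.417) and B lineage genes (0.0578) no longer passed. Without replicate 1 of that group the same held for DNA replication (0.198) and MHC class II genes (0.360). The other 12 tested lists did not pass (adjusted p = 0.127 to 0.857). With the block, their members higher and lower were 4 and 4 for p53 targets, 3 and 2 for literature targets and for interferon-stimulated genes, and 3 and 1 for mitosis. For B cell receptor activation they were 1 and 6, for anti-apoptotic genes 1 and 3, for growth arrest and for NF-kB 2 and 1, and for pro-apoptotic members 1 and 1. Lower alone were 2 plasma cell genes and 1 T cell marker, and higher alone 1 monocyte and macrophage marker. In these the called members included Btg2 (0.62 ± 0.13) of the arrest and p53 lists, Cd44 (-0.76 ± 0.12) of the NF-kB list, Rock1 (-0.58 ± 0.11) of the literature targets, Ddx58 (0.91 ± 0.19) of the interferon list and Bcl2l11 of the pro-apoptotic list. Median and mean differed in sign for literature targets (-0.01 and 0.06) and pro-apoptotic members (0.03 and -0.01).

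The last comparison asks whether genes that can pair with the microRNA differ between the lines as a set. As a set, genes with a site were lower in the miR-148a line by a small amount, carried mainly by genes with the longest site. Of 10836 tested genes with a 3' UTR, 1668 (15.4%) had a 7mer-m8 or 8mer site. Their median log2 fold change lay below that of the other genes by a difference of -0.03 without stimulation (-0.03 and -0.04 in the runs; camera p = 0.0244, p = 0.0914 with an estimated correlation) and -0.05 with anti-IgM (-0.06 and -0.04; camera p = 0.0208, p = 0.0880 with an estimated correlation). Against other genes drawn to match on 3' UTR length and expression (n = 1660 genes of each kind) the differences were -0.05 (camera p = 0.00566) and -0.06 (camera p = 0.0158). For genes with an 8mer (n = 468 genes) the differences were -0.08 (camera p = 1.23e-06) and -0.13 (camera p = 1.57e-06). These 8mer values used the preset correlation, and were not tested with an estimated correlation or with a library left out. Genes with a 7mer-m8 site and no 8mer (n = 1200 genes) did not differ from genes without any site (camera p = 0.255 and 0.173). That test was chosen after the data were seen. Of genes called lower in the miR-148a line, 11 of 27 without stimulation (40.7%; Fisher's exact test, 2-sided, odds ratio 3.80, p = 0.00133) and 50 of 129 with anti-IgM (38.8%; odds ratio 3.55, exact p = 7.86e-11) had a site. Of genes called higher, 2 of 28 without stimulation and 21 with anti-IgM (13.8%) had one. Fisher's test treats genes as independent, which they are not, and takes no account of 3' UTR length or expression. Genes called lower in both conditions with an 8mer include Celf2, Bcat1, Arl6ip1, Adam10, Tpp1, Ywhab and Usp25, named after their values were seen.

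The difference of the site genes (n = 1668 genes, which are not independent replicates) without stimulation no longer passed without replicate 1 of the miR-148a group (-0.02, camera p = 0.147) or replicate 2 of the control group (-0.01, camera p = 0.242). With anti-IgM (n = 1668 genes) it no longer passed without replicate 1 of the miR-148a group (-0.02, camera p = 0.211) or replicate 2 of the control group (-0.02, camera p = 0.0628). Without replicate 1 of the unstimulated control group it was -0.06, without replicate 2 of the unstimulated miR-148a group -0.05, and without replicate 2 of the anti-IgM miR-148a group -0.07. In the responses to anti-IgM and in the interaction, no difference of genes with a site from the others was detected (n = 1668 genes, camera p = 0.944, 0.712 and 0.524).

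**Figure D4:**
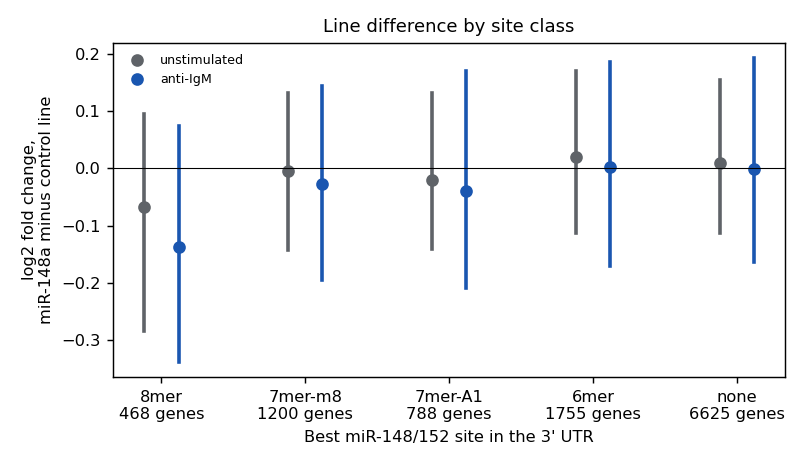
Log2 fold change between the miR-148a and the control line (y axis) by the best miR-148 site in the 3' UTR (x axis, with the number of genes), without (grey) and with anti-IgM (blue). Points are medians and lines run from the lower to the upper quartile over genes, and the 8mer medians are -0.07 and -0.14.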

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

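The list tests of the difference in response and the removal of 1 library were planned, and the tests with thinned libraries and without both anti-IgM libraries of a replicate number were chosen only after the data were seen.

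For 8 gene lists the difference between the responses of the lines passed its own test, which is why they deserve a closer look. The median response in the miR-148a line minus that in the control line, on the log2 scale, was -0.94 for the study list, -0.36 for B cell receptor activation, 0.13 for mitosis, 0.32 for FOXO targets, -0.32 for ribosome biogenesis, -0.33 for cholesterol synthesis, 0.16 for B lineage genes and 0.77 for MHC class II genes. None of them passed with an estimated correlation between genes. The MHC class II value is a difference of responses, and that list lay lower in the miR-148a line in both conditions (medians -1.27 unstimulated and -0.54 with anti-IgM).

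More genes passed in the response of the miR-148a line (3238) than in that of the control line (1925). Unequal depth alone is argued against, because with every library thinned to the smallest total the ratio of the counts was still 1.69. A deviating library remains open: without replicate 2 of the anti-IgM miR-148a group the ratio was 0.782, as was predicted for that case, although a group of 1 library also lowers the count. Without both second-run anti-IgM libraries, so that both lines lose 1, it was 1.16, and without both first-run libraries 2.87. The miR-148a line's count fell little without replicate 1 of its anti-IgM group. It fell far without replicate 1 of its unstimulated group, also a first-run library. Even there it stayed above the control line's count in the same fit. Among fits with 1 library left out, only that without replicate 2 of the anti-IgM miR-148a group put the miR-148a line's count below the control line's. Each such fit leaves a group in 1 run, so it cannot tell a deviating library from the run difference. Among shared genes, which are not independent, the larger change lay in the miR-148a line for 60.4% in the first run and 74.8% in the second. Both lie above the 60% set beforehand, the first barely. The first run's margin is too small to decide, because genes are not independent and each run holds 1 library per group. Fold changes of the same size are thus not settled by these shares. The test shares its estimate of the spread among all groups, so a lower spread in 1 line would not narrow that line's errors alone. A stronger response of the miR-148a line stays untested beyond this.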

How the results depend on the processing

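Thinning, the added correlation settings, the block for overlaps, the paired removal of anti-IgM libraries and the removal of libraries from the seed test were chosen after the data were seen; the other alternatives were planned. Where a library was left out, the lone library of its group is assumed to vary like the other groups, and the count falls partly because fewer samples are left; other causes were not tested.

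Genes called in the control response numbered 3929 with the replicate block, 617 at a threshold of 0.01 (418 higher, 199 lower), 1089 without both first-run anti-IgM libraries, and 540 to 2082 with 1 library left out. In the miR-148a response they numbered 5205 with the block, 1679 at 0.01, 1655 without both second-run anti-IgM libraries and 1481 to 3155 with 1 library left out. Between unstimulated lines they numbered 823 with the block, 179 without a filter, 151 by DESeq2 (61 higher, 90 lower), 30 after thinning (11 higher, 19 lower), 0 at 0.01 and 0 to 76 with 1 library left out. Between anti-IgM lines they numbered 1822 with the block, 450 without a filter, 16 with only the groups compared, 3 at 0.01 and 0 to 222 with 1 library left out. The interaction had 11 with the block, 1 by DESeq2 and 0 to 0 with 1 library left out. The control response split into 972 higher and 1244 lower genes without a filter, 827 and 883 by DESeq2, and 474 and 173 without replicate 1 of the anti-IgM control group, against 1084 and 841. RLE size factors moved no split by over 10 points, and no called list changed the sign of its median with RLE or DESeq2 scaling.

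Lists called in the control response were 10, and 1 with an estimated correlation (interferon), 0 with that and the replicate block, 20 by fry's mixed test and 9 to 12 with 1 library left out. For the miR-148a response they were 11, then 0, 0, 20 and 11 to 14. For unstimulated lines they were 4, then 0, 0, 7 (MHC class II not among them) and 4 to 5, and 0 by fry's directional test. For anti-IgM lines they were 10, then 0, 0 and 7 to 11, and 3 by the directional test. For the interaction they were 8, then 0, 0, 1 by the mixed test and 5 to 11, and 0 by the directional test. Shared calls of the responses were 539 at 0.01 and 3288 with the block, and of the line differences 0 and 469. The seed-site difference stayed at -0.0296 and -0.0498 with an estimated correlation but no longer passed, and was -0.0543 and -0.0587 against the matched background. It ran from -0.0609 to -0.00614 and from -0.0749 to -0.0222 with 1 library left out.

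Reversed were Gadd45a in the control response after thinning (-0.18) and Gadd45a between anti-IgM lines without replicate 1 of the anti-IgM control (0.061) or replicate 2 of the anti-IgM miR-148a group (0.02). None of these had passed. With 1 library left out, Gadd45a ran from -0.72 to 0.061 between anti-IgM lines, 0.28 to 1.59 between unstimulated lines, 0.17 to 1.302 in the control response and -1.01 to -0.02 in the miR-148a response. Apart from the values given with the results, the block changed no call of a reported gene or list. Of 235 named-gene results, RLE weakened 3, limma-voom 8, DESeq2 5 of 228 and the libraries of the groups alone 43 of 232. With 1 library left out, 455 of 1880 values lost their call.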

Other observations

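The tests of the MHC class II pattern, the choice of the histone genes, the tests of site classes, of 3' UTR trends and of an estimated correlation for the seed sites, and the naming of genes in the next 2 paragraphs were chosen only after the results or the data were seen. The ranking of the seed word and the test of 8mer sites were planned.

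Genes of the run difference have not been described above. With the block, 2123 genes differed between the runs, 1098 higher and 1025 lower in the second. Replication-dependent histone genes, whose transcripts mostly lack a polyA tail, were picked because they made up 22 of the 40 largest differences among called genes with a log2 CPM of at least 1. Of 52 measured Hist genes 42 were higher in the second run and 0 lower, with a median log2 difference of 2.44. Hist1h1e differed by 4.81 ± 0.22, Hist2h3c2 by 4.08 ± 0.19 and Hist1h2ap by 3.602 ± 0.11, and histone copies are so alike that reads can be shared. Of the planned lists, p53 targets were lower in the second run (median -0.22, adjusted p = 2.04e-06), heat shock genes lower (-0.26, adjusted p = 0.00676) and NF-kB genes higher (0.12, adjusted p = 0.00676), and each had an adjusted p of 0.915 with an estimated correlation. DNA replication genes had a median of -0.01.

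Genes lower in both line comparisons include Pdia3, an endoplasmic reticulum isomerase (-0.94 ± 0.13 without and -0.77 ± 0.13 with anti-IgM), the chaperone Calr, the vacuolar ATPase protein Atp6ap2 (-0.93 ± 0.15 and -1.13 ± 0.16) and the sheddase Adam10 (-0.72 ± 0.09 and -0.81 ± 0.09). Genes higher in both include Glul, glutamine synthetase (0.83 ± 0.11 and 0.95 ± 0.11), Plcb2 (1.002 ± 0.13 and 0.89 ± 0.13) and Klf3 (0.82 ± 0.14 and 1.08 ± 0.13).

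Genes with a miR-148 site were slightly lower in the miR-148a line. Base composition is argued against, since the seed word ranked 2 and 5 of 603 words of the same bases, and none of the others was as low in both conditions. A trend with 3' UTR length, GC content and expression is argued against as the whole cause. With these in a linear model the site coefficient was -0.0736 (SE 0.00974) and -0.0746 (SE 0.0108). The coefficient compares means rather than medians. Its SE treats genes as independent, which they are not, so this argument is weaker than the SE implies. Repression by pairing is consistent with medians, relative to genes without any site, of -0.0775 and -0.136 for 8mer, -0.0136 and -0.0253 for 7mer-m8 and 0.00953 and 0.00392 for 6mer genes, although 7mer-A1 genes (-0.0307 and -0.0376) lay below 7mer-m8 genes, against the usual order. It remains a hypothesis, as the set's p did not pass with an estimated correlation or without some of the libraries.

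MHC class II genes were lower in the unstimulated miR-148a line. Direct pairing as the cause for the whole group is argued against, because 2 of 11 members, Ciita and H2-DMa, have a 7mer-m8 site, while an effect through the activator Ciita was not tested. A pattern from 1 run alone is argued against by medians of -1.10 in the second and -1.34 in the first run. A shift shared by all libraries of a run cancels in these values, because each run holds 1 library of every group. Monocytes or macrophages among the control cells are argued against, because Lyz2 reached 0 CPM (0 counts in both unstimulated control libraries) and Csf1r 0.264 CPM before TMM scaling there, although Fcgr1 of the same list was at -1.15 ± 0.41 in the line difference (adjusted p = 0.309, and 0.0301 with the block) and the list's median at -0.38. A difference that arose between the 2 stable lines apart from the microRNA may also give this pattern and was not tested, since each condition has 1 line.

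Loss of B lineage identity was also considered for the MHC class II pattern. The B lineage list had a median of 0.01 between the unstimulated lines, with 6 members higher and 4 lower with the block. This test was set aside after the median had been seen, because members that go both ways decide nothing.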
